A study of Caenorhabditis elegans with 2 samples.

How the data were processed

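The series holds ChIP-seq of eGFP-tagged SMA-9 from whole L2 larvae of strain OP130, with 2 biological replicates in 1 group, as numbered in the labels. The labels name the antibody by the target, sma-9, and describe the experiment as directed at an eGFP fusion. For each replicate and for the pooled reads, the authors deposited a relaxed list of peaks and background made as input for the irreproducible discovery rate procedure, in the ce10 and ce11 builds. They also deposited a thresholded list derived from the pooled and replicate lists. Per the text that accompanies the deposited lists, they were called against a control. The aligner, the peak caller and the rate threshold are not given in the sources used here. Control libraries and coverage tracks were not used here.

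The deposited lists give each peak's position, a signal and a score. The signal in column 7 is the authors' peak signal, never below 0, with no scale stated. Its median differs between lists, so lists were compared by rank or by ratio. The score in column 9 is the authors' significance value per the narrowPeak layout of the deposited lists. It lies below 0 for 20593 peaks (68.6%) of the pooled list in ce11, which a negative log of a probability cannot, so it was treated as a score of unknown scale and used only to rank. All 8 lists have peaks of a single width per list and a summit at the centre, so a summit here is a peak centre. Every relaxed list has 30000 peaks, so its length says nothing about the number of bound sites. The thresholded list is the 125 peaks with the highest signal of the pooled list in ce11, and the 111 highest in ce10, as tested on the lists. It holds no rate per peak. Read depth is unknown, so no interval that needs it is given, and exact 95% (Clopper-Pearson) intervals of shares cover counting error over peaks only.

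Positions were annotated with Ensembl release 115 genes of WBcel235, which has the coordinates of ce11, and sequence came from the RefSeq assembly of the same build, 100.3 Mb over 6 nuclear chromosomes. Coordinates are 1-based. The ce10 lists were used without annotation. A summit was called at a start when it lay from 500 bp upstream to 200 bp downstream of an annotated transcript start or gene 5' end of any class. Features were assigned in the order coding exon, 5' UTR, 3' UTR, noncoding RNA exon, pseudogene, intron of a coding gene, intron of a noncoding gene, between genes. Noncoding RNA genes were counted within 200 bp of a summit.

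Thresholded peaks were compared with the 29849 pooled peaks that overlap none of them, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family (6 chromosomes, 19 gene lists, 17 motifs, the RNA classes and the features). GC content of 200 bp windows was compared by a permutation test of the difference of means with 100000 resamples. Motif windows of 200 bp were compared with 20 background peaks per thresholded peak matched on GC (mean 45.5% against 46.2%). Gene lists and motifs were fixed before the data were examined. Genes were called with a summit from 1 kb upstream to 500 bp downstream of a start, among the 19585 genes of any class with any pooled summit there. Replicate lists were compared by overlap of at least 1 bp of their 125 strongest peaks, with the ranks of replicate 2 shuffled, and by correlation across peaks matched one to one by nearest summit. Since there is 1 group, no comparison between groups was possible.

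Genes are named by a rule written before the data were examined. It takes the 20 thresholded peaks of highest signal with the gene of the nearest start and any other within 1 kb, up to 6 members per list with a thresholded summit, sma-9 and unc-119, and the 5 largest and 5 smallest ratios between replicates. A peak absent from 1 replicate's list is named as such, and the best-placed member of a list without a thresholded peak and genes given as motif examples were chosen after their values were seen. Other genes outside the rule are said to be chosen afterwards. Features, the split of ncRNA and piRNA genes and the nearest coding start were examined after the values were seen.

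The main tests were tested on simulated data. Of 60 shared peaks placed in a pair of simulated lists, 60 were found, and 0 of 20 unrelated pairs passed. With 125 peaks drawn at random from the other pooled peaks in 40 draws, the start share passed in 3, the noncoding, X and GC tests in 1 each, any gene list in 0 and any motif in 2. The list test called nuclear hormone receptors in 20 of 20 draws when 5 of 125 peaks were placed at such genes, and the motif test called GAGAGA in 20 of 20 when it was written into 40 of 125 windows. In the list draws, the remaining peaks were random pooled peaks away from such genes. The data also had 5 such genes at thresholded peaks, and the list did not pass (Fisher's exact test, adjusted p = 0.058). The draws therefore do not give the power of the list test in the data. The draws with GAGAGA written in had no GC matching, unlike the main motif test. GAGAGA was in 10.2% of windows over all other pooled peaks and in 21.4% of the matched ones. Those draws therefore do not give the power of the motif test either. Alternatives covered the build, the overlap rule, the number of top peaks, the ranking column, windows, backgrounds, the strongest 62 peaks, each replicate's own peaks and the transgene loci. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.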

Results

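Binding of SMA-9 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole second larval stage (L2) Caenorhabditis elegans of mixed sex. SMA-9 is a large zinc finger protein related to fly Schnurri. It acts with the SMAD proteins of the BMP-like Sma/Mab pathway in body size, and it also has a role in mesoderm patterning. The strain, OP130, carries an integrated transgene with an eGFP-tagged sma-9 and is marked by unc-119. The only group had 2 biological replicates. Each replicate had a relaxed list of 30000 peaks, and the pooled reads gave another list of the same length. A thresholded list of 125 peaks, each 384 bp wide, was derived from these in the ce11 build. Peak signal is the authors' own value per peak, with a median of 9.50 in replicate 1, 6.34 in replicate 2 and 14.1 in the pooled list. Read depth per library is unknown from these lists. No control library was used here, so all comparisons are between sets of peaks, which are units within these 2 libraries and not independent replicates.

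The first comparison asked where the strongest binding lay. The strongest thresholded peaks lay in a single intron of pqn-41, at mdl-1, at nhr-1, nhr-3 and nhr-14, and beside small noncoding RNA genes. Of the 20 strongest peaks, 9 had their summit in an intron of a coding gene, and 17 were overlapped by one of the 125 strongest peaks of each replicate. The strongest peak of all had a pooled signal of 157 and ranked 1 in both replicates. It lay at III:1925176-1925559 in the gene pqn-41 (WBGene00004128, III:1905958-1939570, plus strand), which encodes a glutamine-rich protein that acts in the death of the linker cell. Peaks of rank 3 (signal 103), 11 (72.4) and 58 (44.6) lay in the same intron, so that 4 summits fell within 5.13 kb. The intron spans III:1919901-1927670, and 0 exons of this gene are annotated inside it. It lies between annotated starts of pqn-41 at III:1919571 and III:1927671. The summits of rank 1, 11 and 58 lay 2303, 1072 and 3973 bp upstream of the latter, and that of rank 3 lay 1898 bp downstream of the former.

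**Figure D1:**
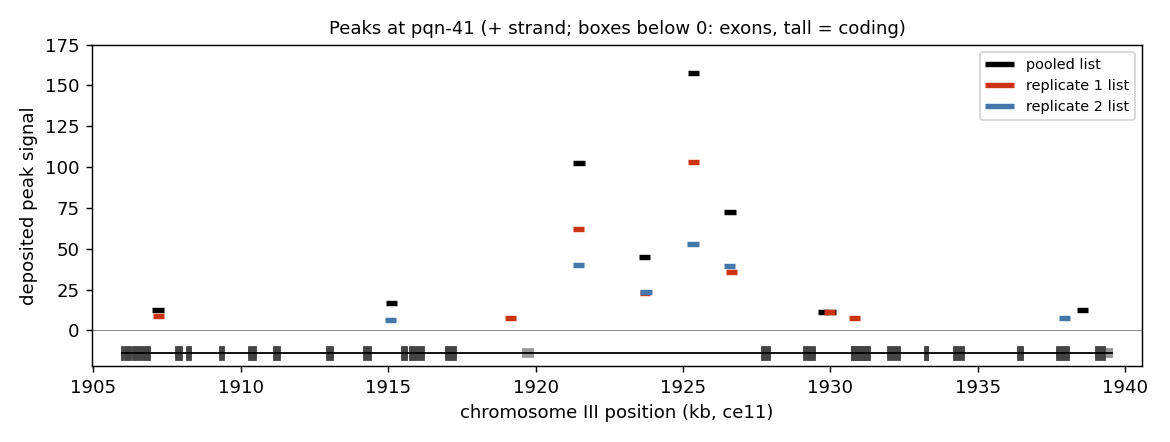
Peaks in the 3 relaxed lists across pqn-41 on chromosome III, with position in kb on the x axis and the deposited peak signal on the y axis, where horizontal marks are peaks at their own width and boxes below 0 are exons. The 4 thresholded peaks, with pooled signals from 44.6 to 157, sit together in an intron of 7770 bp.

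Other strong peaks lay at mdl-1, dmd-7, zfp-1, let-526 and Y111B2A.12. At rank 4 (signal 101) a peak had its summit at X:6742252 between genes, 99 bp upstream of mdl-1 (WBGene00003163), which encodes a MAD-like basic helix-loop-helix protein, and within 1 kb of the start of the noncoding gene R03E9.9. At rank 6 (84.7) the summit lay at V:6246715 in exons of the noncoding genes K08B12.6 and K08B12.8, 216 bp upstream of the DM-domain gene dmd-7. Introns of zfp-1, the homologue of the chromatin factor AF10, held the peaks of rank 18 (63.4) and 19 (61.5). Another, of rank 20 (61.4), lay in an exon of the noncoding gene F48C1.15 inside let-526, which encodes a subunit of the SWI/SNF complex, and also within 1 kb of F48C1.13. Rank 2 (108) was a peak in an intron of Y111B2A.12, 3349 bp downstream of the nearest start of the gene.

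Of the 20 strongest peaks, 4 lay in or upstream of the nuclear hormone receptor genes nhr-1, nhr-3 and nhr-14. A peak of rank 10 (72.6) lay 316 bp upstream of nhr-1, and that of rank 15 (66.9) lay 8127 bp upstream of the same gene. An intron of nhr-3 held the peak of rank 12 (71.1), 1209 bp from the nearest start, that of the noncoding gene H01A20.4. Between genes, 1420 bp upstream of nhr-14, lay the peak of rank 14 (68.7), whose nearest start at 1219 bp is that of the noncoding gene T01B10.13.

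The remaining peaks of the 20 strongest were spread over other coding and noncoding loci. Rank 5 (85.7) lay 1388 bp from the piRNA gene 21ur-13313 and 1988 bp upstream of sup-26, which encodes an RNA-binding protein. Rank 7 (78.2) lay in an intron of mom-1, the Porcupine homologue of Wnt secretion, with the start of cest-16 nearest at 3370 bp. Rank 8 (76.0) was nearest an unnamed tRNA gene (WBGene00014538) at 1537 bp. Rank 9 (75.3) lay among 8 piRNA genes within 1 kb, the nearest being 21ur-865 at 443 bp. A peak of rank 13 (69.6) lay 367 bp from the start of the noncoding gene T14G8.5, and that of rank 16 (65.2) in exons of T23F11.10 and T23F11.7, 1012 bp upstream of the phosphatase gene ppm-2. Rank 17 (63.998) lay in an intron of the trehalase gene tre-2, 207 bp from T05A12.7.

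The next comparison asked how far the replicates shared these peaks. Of the 125 strongest peaks of replicate 1, 41 (32.8%) overlapped one of the 125 strongest of replicate 2 by at least 1 bp. Shuffling the ranks of replicate 2 gave 0.536 on average and 6 at most in 100000 resamples (one-sided permutation test, p = 1e-05, the smallest it can give). The shared number was 82 of the top 500, and the fraction fell to 11.6% of the top 1000 (116 against 20.3 by chance) and 12.1% of the top 5000 (607 against 386), with the same permutation p. All 125 thresholded peaks were present in the relaxed list of replicate 1 and 120 in that of replicate 2. By strength the lists differed more, as 90 thresholded peaks were overlapped by a top peak of replicate 1, 62 by a top peak of replicate 2, 41 by both and 14 by neither. Ranks beyond 1000 occurred at 34 thresholded peaks in replicate 2 and at 6 in replicate 1.

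Signal in the 2 lists was only weakly related across matched peaks. Over 9578 peaks matched one to one, Spearman's rho was 0.0871 and Pearson's r of log2 signal was 0.185 (permutation p = 1e-05 for each, the smallest possible). Among the 120 thresholded peaks present in both, rho was -0.0190 (permutation p = 0.837) and r was 0.0958 (p = 0.299), values that are lowered by construction, since these peaks are those of highest pooled signal. These correlations are across peaks, which are not independent replicates. The log2 ratio of replicate 1 to replicate 2 signal at these 120 peaks had a median of 0.96 with an SD over peaks of 0.82. Dividing each list by its own median signal brought the median ratio to 0.38.

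**Figure D2:**
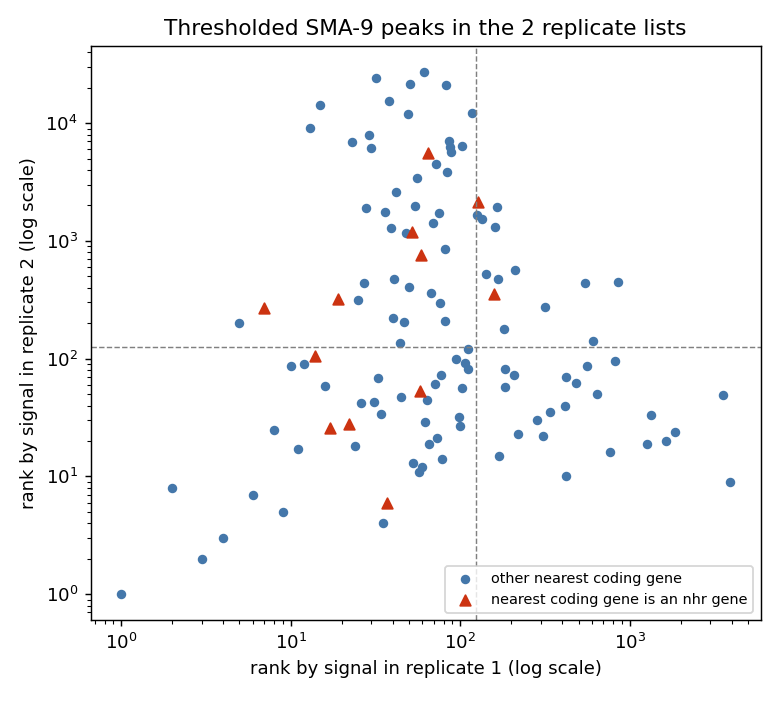
Rank by signal of each thresholded peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), for the 120 peaks present in both, where dashed lines mark rank 125 and triangles mark peaks whose nearest coding start belongs to an nhr gene. Peaks strong in both are at the lower left, and a column of peaks strong in replicate 1 reaches rank 27189 in replicate 2.

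Single loci show the range. The ratio to replicate 2 was largest at the peak of rank 20 in let-526, at a log2 ratio of 2.90 (rank 15 in replicate 1 and 14401 in replicate 2). It was 2.82 at the noncoding gene C17G10.11, 2.71 at the phospholipase gene ipla-6, 2.61 near D2023.16 and 2.52 near Y37D8A.5. At the other end were peb-1 at -1.13 (rank 3914 in replicate 1 and 9 in replicate 2), din-1 at -0.57, ppfr-1 at -0.52, nphp-1 at -0.51 and the SL2 RNA gene sls-2.1 at -0.46. The last of these matched a replicate 2 peak that another thresholded peak at sls-2.1, of rank 35, also matched. The 5 peaks absent from the list of replicate 2 were those nearest C49F8.10, the pseudogene WBGene00012384, T27A8.8, ogt-1 and 21ur-12946. In replicate 1 they ranked 20, 74, 18, 21 and 108 in that order, and they do not enter the ratios and correlations at thresholded peaks.

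Thresholded peaks were then compared with the 29849 pooled peaks that overlap none of them. Of the 125, 30 lay within 10 kb of another thresholded peak, and the tests count each peak as separate. Summits lay at an annotated start, from 500 bp upstream to 200 bp downstream, for 63 of 125 thresholded peaks (50.4%, exact 95% interval 41.3% to 59.5%) against 27.7% of the others. The odds ratio was 2.65 (Fisher's exact test, two-sided, p = 1.05e-07). With starts of protein-coding genes alone the shares were 27.2% and 17.5%, an odds ratio of 1.76 (exact p = 0.00656). The median distance to the nearest coding start was nevertheless longer, at 1698 bp against 1247 bp, a difference that was not tested. Within 2 kb of a start the shares were 80.8% and 80.7%, an odds ratio of 1.01. Without replicate 1 the odds ratio at starts was 1.69 (exact p = 0.00612). Coding exons held 3 thresholded summits (2.4%) against 22.6% of the others, an odds ratio of 0.0842 (Fisher's exact test, adjusted p = 8.41e-10). Exons of noncoding RNA genes held 22 (17.6%) against 1.57% (odds ratio 13.4, adjusted exact p = 8.9e-16). Summits between genes made up 48% against 35.003% (odds ratio 1.71, adjusted exact p = 0.0091). Introns held 31.2% and 32.5% (odds ratio 0.941, adjusted exact p = 0.969).

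Thresholded summits also lay at small noncoding RNA genes more often than other peaks did. This share is not separate from the start share, which counted starts of any class, as ncRNA genes have a median length of 140 bp. No comparison of this share was matched on GC. A small noncoding RNA gene lay within 200 bp of 34 thresholded summits (27.2%, exact 95% interval 19.6% to 35.9%) against 8.05% of the others, an odds ratio of 4.27 (Fisher's exact test, p = 2.11e-10), and 2.80 without replicate 1. The class of ncRNA and piRNA genes gave 32 of these peaks (25.6% against 7.63%, odds ratio 4.17, adjusted exact p = 6.81e-09). Within it, 31 summits had an ncRNA gene and 1 had a piRNA gene (odds ratios 7.80 and 0.214, adjusted exact p = 9.44e-16 and 0.141), a split made after the values were seen. The snRNA class had 4 peaks (3.20% against 0.0804%, odds ratio 41.1, adjusted exact p = 1.91e-05). All 4 lay at genes for SL2 spliced leader RNA, the trans-splicing donor for downstream genes of operons, and these genes were picked out after their values were seen. At rank 33 (signal 52.4) a summit lay 35 bp upstream of sls-2.2, with sls-2.3 within 1 kb. Peaks of rank 35 (51.3) and 113 (35.8) lay 34 bp upstream and 179 bp downstream of the start of sls-2.1, and that of rank 89 (38.9) was 19 bp into sls-2.4. The peaks of rank 35 and 113 overlap each other, so the test of the snRNA class counts this locus more than once. SL2 RNA is encoded by a family of 18 annotated genes, and how reads were placed among its members was not tested, so these values are uncertain. The snoRNA class (2 peaks, adjusted exact p = 0.0788), tRNA class (1 peak, adjusted p = 0.471), lincRNA and antisense class (2 peaks, adjusted p = 0.18), miRNA class (0 peaks) and rRNA class (0 peaks) did not pass.

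By chromosome, 37 of 125 thresholded peaks (29.6%, exact 95% interval 21.8% to 38.4%) lay on X against 22.3% of the others, an odds ratio of 1.46 that did not pass (Fisher's exact test, p = 0.0665). Of the 20 strongest peaks, 8 lay on X. The call depended on the set compared. With each replicate's own 125 strongest peaks the share on X was 35.2% for replicate 2 alone (odds ratio 2.00, exact p = 0.000405) and 32% for replicate 1 alone (odds ratio 1.69, p = 0.00876), and against chromosome length (17.7%) p was 0.000952. Against the next 1000 peaks, 26.1% of which lay on X, the odds ratio was 1.19 (exact p = 0.391). No chromosome passed after adjustment over the 6 (lowest adjusted exact p = 0.327, on I and X). On autosomes, 29 of 88 peaks (32.95%) lay in the outer 25% at either end of the chromosome against 40.5% of the others (odds ratio 0.723, exact p = 0.159). On X, 20 of 37 (54.1%) did so against 45.8% (exact p = 0.326). Without replicate 2 the autosomal difference passed (odds ratio 0.607, exact p = 0.0356).

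Thresholded summits were rich in G and C. GC content over 200 bp averaged 46.2% (SD 7.30 over 125 peaks) against 34.7% (SD 6.79) in the others, a difference of 11.6 percentage points (permutation test, p = 1e-05, the smallest it can give). Windows 1 kb to either side of the same summits averaged 36.4%, and the 6 chromosomes 35.4%. Without replicate 1 the difference was 7.44 points (permutation p = 1e-05).

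Among 17 motifs fixed before the data were examined, 7 were more frequent and 1 less frequent in thresholded windows than in 2500 GC-matched windows of other peaks. The share with GAGAGA was 55.2% against 21.4% (odds ratio 4.54, Fisher's exact test, adjusted p = 2.05e-14). The E-box CACGTG, bound by basic helix-loop-helix proteins, was in 19.2% against 6.68% (odds ratio 3.32, adjusted exact p = 3.25e-05), among them the windows at mdl-1 and adh-1. The SMAD box GTCT, the core of SMAD binding sites, was in 88.8% against 70.96% (odds ratio 3.24, adjusted exact p = 3.25e-05). The GC-rich SMAD site GGCGCC was in 11.2% against 4.84% (odds ratio 2.48, adjusted exact p = 0.0128). The kappa B-like site GGGRNNYYCC, a class of site bound by vertebrate relatives of Schnurri, was in 8% against 2.28% (odds ratio 3.73, adjusted exact p = 0.00436), including the windows near sup-26 and ppm-2. The GATA site WGATAR was in 43.2% against 30.6% (odds ratio 1.72, adjusted exact p = 0.0128), and the GC box GGGCGG in 14.4% against 7.12% (odds ratio 2.19, adjusted p = 0.0128). The ETS site CCGGAAR was in 0.8% against 5.8% (odds ratio 0.131, adjusted exact p = 0.0297).

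The other 9 motifs did not pass. The fly SMAD and Schnurri silencer element was found in 0 thresholded windows and in 0.04% of the matched windows. The SMAD palindrome GTCTAGAC was in 1 thresholded window (0.8%) against 0.2% (odds ratio 4.02). Both are too rare in the matched windows for the test to decide on their use. The nuclear receptor site AGGTCA was in 5.60% against 7.04% (adjusted exact p = 0.837). Adjusted p was also 0.837 for GGCCG and the AP-1 site, 0.688 for the forkhead, CRE and Hox-Pbx sites, 0.48 for the SMAD palindrome and 1 for the T-box site and the silencer element. Calls for GAGAGA and the E-box held with either replicate's own peaks, at odds ratios of 2.51 for GAGAGA (adjusted exact p = 0.000224) and 2.36 for the E-box (adjusted exact p = 0.0393) without replicate 1. Without replicate 1 the SMAD box (odds ratio 1.51, adjusted exact p = 0.146), the GC-rich SMAD site (2.07, 0.119), the kappa B-like site (2.28, 0.146), WGATAR (1.27, 0.392) and the ETS site (0.248, 0.119) no longer passed, which left 3 motifs. Without replicate 2 the GC-rich SMAD site (1.86, 0.246) and the GC box (1.33, 0.687) did not. With the 62 strongest peaks GAGAGA and the E-box alone passed. The motif tests against the next 1000 peaks and against windows 500 bp to either side had no GC matching. All 998 of the next peaks that overlap no thresholded peak were used, at a mean GC of 35.9% against 46.2%. Values from these tests therefore mix the motif with the difference in GC. The call for WGATAR was also lost against the next 1000 peaks (0.961, adjusted exact p = 1), without GC matching (1.19, 0.555) and against windows 500 bp to either side (1.35, 0.38). The call for the ETS site, found in 1 thresholded window, was also lost against the next 1000 peaks (0.188, adjusted exact p = 0.164), in 100 bp windows (0.302, 0.632), against windows 500 bp to either side (0.280, 0.525) and without GC matching (0.160, 0.0691). In 100 bp windows the GC-rich SMAD site (2.12, adjusted exact p = 0.213) and the GC box (2.02, 0.135) did not pass. GGCCG passed where GC was not matched, against the next 1000 peaks (2.75, adjusted exact p = 0.001), windows 500 bp to either side (2.21, 0.0406) and all other pooled peaks (3.22, 2.41e-05).

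**Figure D3:**
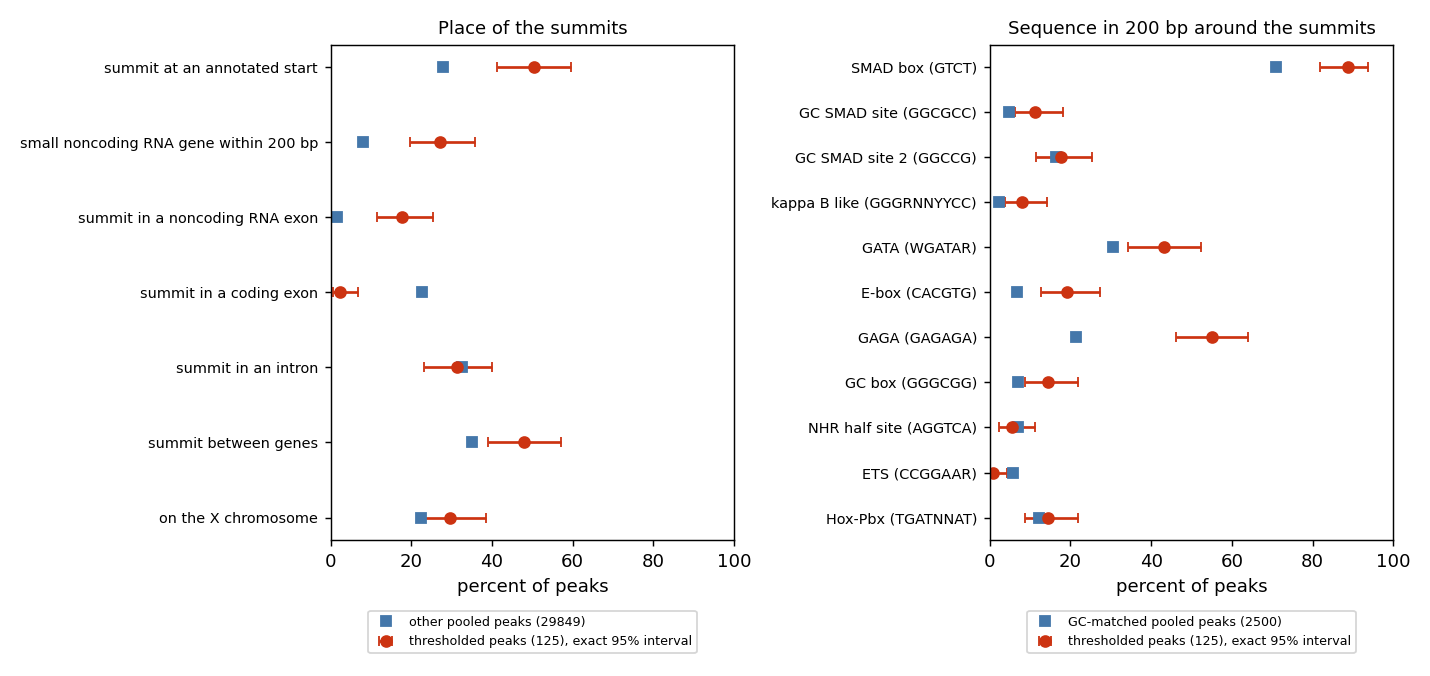
Percent of thresholded peaks (circles, with exact 95% intervals, 125 peaks) and of comparison peaks (squares) by place of the summit at the left and by sequence at the right, with 29849 other pooled peaks at the left and 2500 GC-matched peaks at the right for comparison. Starts, noncoding RNA exons, GAGAGA and the E-box lie above the comparison peaks, and coding exons lie below.

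Gene lists asked whether the peaks marked the pathway and tissues in which sma-9 is known to act. None of the 19 lists passed with starts from 1 kb upstream to 500 bp downstream (Fisher's exact test, 0 lists at adjusted p under 0.05, 1 at an unadjusted p under 0.05), and 15 lists had 0 members at a thresholded peak. The genes compared were of any class, and 8519 of the 19585 were protein-coding, as were 46 of the 140 called. Of the 20 Sma/Mab pathway members, 8 had any pooled peak in the window. Of these 8, 0 had a thresholded one, against 0.715% of other genes of any class and 0.540% of other coding genes. The best-placed member was daf-4, the type II receptor, at rank 1309 of the pooled list. The best-placed member of the DAF-7 pathway list was daf-3, at rank 1131. Cuticle collagens and body size genes had 0 of 75, with col-63 best placed at rank 170. Hox genes (0 of 6), mesoderm genes (0 of 11), hypodermis genes (0 of 13), heterochronic genes (0 of 14, with nhr-23 best placed at rank 1527), homeobox genes (0 of 42, with unc-30 at rank 199) and innate immunity genes (0 of 10) had none. Histones (0 of 5), heat shock genes (0 of 6) and markers of intestine (0 of 9), body muscle (0 of 9), neurons (0 of 7) and germline (0 of 4) also had none, as did the DAF-7 pathway (0 of 3). With lists this small the exact 95% intervals are wide, and that of the Sma/Mab pathway reaches 36.9% over the 8 members with a pooled peak and 16.8% over all 20.

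Nuclear hormone receptors came nearest to the threshold, with 5 of 137 genes (3.65%, exact 95% interval 1.20% to 8.31%) against 0.694% of other genes of any class (odds ratio 5.42, Fisher's exact test, p = 0.00305, adjusted p = 0.058). The 5 were nhr-1 (signal 72.6), nhr-48 (60.1), nhr-58 (42.4), nhr-68 (40.5) and nhr-105 (34.95), with summits from 82 bp to 569 bp upstream of a start. Their ranks in replicates 1 and 2 were 37 and 6 for nhr-1 and 22 and 28 for nhr-48. For nhr-58 they were 65 and 5623, for nhr-68 209 and 73, and for nhr-105 128 and 2149. For nhr-68 the start of H12C20.7 lay nearer, at 71 bp. The list passed when each summit was given to its nearest start alone (8 of 184 genes, odds ratio 7.34, adjusted exact p = 0.000536) and against all protein-coding genes (odds ratio 8.91, adjusted p = 0.0077). Among protein-coding genes with a pooled summit in the window, an alternative chosen afterwards, the list also passed. There it was 5 of 137 against 0.489% of other coding genes (odds ratio 7.71, adjusted exact p = 0.0153). Among genes of any class, without replicate 2, the list had 3 of 126 genes (odds ratio 3.48, adjusted exact p = 0.917). With the 62 strongest peaks it was 2 of 135 genes (odds ratio 4.34, adjusted exact p = 0.783). Single members of 3 other lists had a peak. These were fat-6, a stearoyl-CoA desaturase (signal 36.4, 321 bp upstream and in a coding exon of ZK822.9, adjusted p of its list 0.564), rpl-35 (36.7, 353 bp upstream, adjusted exact p = 0.723) and the pharyngeal factor peb-1 (45.1, 445 bp upstream of a start, adjusted p = 0.53).

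The annotated loci of sma-9 and unc-119, called the transgene loci here, had no thresholded peak. The site where the transgene is integrated was not located. Within 20 kb of sma-9 (WBGene00004862, X:10769282-10782973) the pooled list had 3 peaks, the strongest with a signal of 18.04 at rank 5645, and within 5 kb of unc-119 (WBGene00006843, III:10902641-10908935) it had 1 with a signal of 12.3. Together these 4 pooled peaks were 5.72 per 100 kb against 29.8 over the genome, a lower density that was not tested. Separately, with 4 of 29849 other peaks at these loci, a count of 0 among the 125 thresholded peaks is not informative. Without replicate 2 the loci held 7 relaxed peaks, or 10.002 per 100 kb.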

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

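Alternatives were fixed before the data were examined except 4 chosen afterwards: starts of protein-coding genes against random positions, noncoding RNA without ncRNA and piRNA genes, and for gene lists protein-coding genes with a relaxed peak and nearest protein-coding starts. Over the main results, 57 recomputed values kept their direction and side of the threshold, or stayed within the spread. Counts were taken as kept when within a fixed factor. Of the rest, 12 counts moved, 3 values reversed, 7 passed where the main value had not and 1 no longer passed. For single lists and motifs, 49 were kept, 4 reversed, 8 came to pass and 21 no longer passed. Leaving out the transgene loci removed 0 thresholded peaks, so it could change little. The noncoding RNA share and the GC difference kept direction and side under every alternative run, and odds ratios of the noncoding RNA share ran from 2.80 to 7.88. The replicate overlap stayed past its threshold, while the shared fraction fell from 32.8% to 11.6% for the top 1000 peaks. The median log2 replicate ratio fell from 0.96 to 0.38 when each list was divided by its own median, within the SD over peaks of 0.82, which is too wide a bound to show that it is stable. The cause of the changes below was not tested unless stated. The peak count fell to 62 for the stronger peaks of the list by signal and to 41 for peaks overlapped by a top peak of each replicate, both by construction. Spearman's rho was -0.0190 among thresholded peaks, chosen by pooled signal, and -0.467 when unmatched peaks took the lowest signal of the other list, and both choices lower it by construction. The odds ratio of the start share fell to 1.01 within 2 kb either side. For X it passed the threshold for the stronger part of the list (1.78), chromosome length (1.96) and ce10 (1.60), and with single replicates (1.69 to 2.00), but was 1.19 against the next 1000 peaks. For arms it turned to 1.19 against the next 1000 peaks and passed against chromosome length (0.492), with single replicates at 0.607 to 0.664. Passing gene lists rose from 0 to 1, nuclear hormone receptors each time, with a 2 kb window, all protein-coding genes, nearest starts, and with both alternatives chosen afterwards. Passing motifs fell from 8 to 2 in the stronger part of the list, which has fewer peaks, to 5 with 100 bp windows, and to 3 to 6 with single replicates. Peaks at the transgene loci fell from 4 to 0 with narrower windows and were 4 to 7 with single replicates. GGCCG turned to 0.932 (stronger part of the list), 0.948 (100 bp) and 0.675 (without replicate 2, against 1.04 without replicate 1). It passed where GC was not matched, at 2.75 (next 1000 peaks), 2.21 (windows 500 bp to either side) and 3.22 (all other pooled peaks). WGATAR turned to 0.961 against the next 1000 peaks, which were not matched on GC. The transgene loci were not run in ce10, for which no annotation was used here. A stricter rate threshold was replaced by the stronger peaks by signal, since the lists hold no rate. Read depth, unknown here, limits how far weak peaks in replicate 2 can be read.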

Other observations

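The several-peak genes, lag-1, skn-1, hif-1 and egl-9, the correlates of the replicate ratio, the nearest coding start, the tests of signal against GC, among other pooled and among thresholded peaks, and of autosomal nuclear hormone receptor genes, and the hexamer values without AGAGAG were chosen after the values they rest on were seen. In all, 13 genes were the nearest coding start of more than 1 thresholded peak. A pair of peaks lay in the MAP kinase phosphatase gene vhp-1 (rank 23, signal 59.7, and rank 100, 37.1), in let-526 (61.4 and 49.2), in pkg-2, a cGMP-dependent protein kinase gene (55.8 and 44.4), and at din-1, which encodes a cofactor of the nuclear receptor DAF-12 (54.1 and 46.7). Introns of lag-1, the effector of Notch signalling, and of skn-1, the homologue of NRF factors, held peaks with signals of 56.96 and 51.1. Both hif-1 (50.1) and egl-9, the prolyl hydroxylase that acts on HIF-1 (45.7), had a peak upstream of their start, at 1983 bp and 1762 bp.

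The share of soft-masked bases, a mark of repeats in the reference, was 17.5% (SD 13.8) in thresholded peaks and 31.9% (SD 19.3) in the others (permutation test, p = 1e-05, the smallest it can give). Across the 120 thresholded peaks present in both replicates, the log2 ratio of replicate 1 to replicate 2 fell with GC content (rho = -0.243, permutation p = 0.00747, adjusted p = 0.0299 over 4 measures, and r = -0.190, adjusted p = 0.0754) and rose with distance to the nearest coding start (rho = 0.215, adjusted p = 0.0373, and r = 0.208, adjusted p = 0.0754). It showed no such relation to masked bases (rho = 0.0751, adjusted p = 0.555) or pooled signal (rho = 0.0412, adjusted p = 0.654). These are across peaks of 2 libraries.

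The design has a single group, so no biological explanation was tested. The first pattern is the GC content of thresholded summits. Position within the start windows does not account for it. Among the 62 thresholded summits outside these windows the difference was still 11.045 percentage points (45.8% against 34.8%, permutation p = 1e-05). Starts farther from the summit, or not annotated, were not tested. A signal that rises with GC in these libraries stays open. Signal and GC had a rank correlation of 0.0110 over the 29849 other pooled peaks, but these leave out the peaks that form the pattern, among which it was 0.259 (125 peaks, permutation p = 0.00372).

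The second pattern is the set of nuclear hormone receptor genes. Such a gene had the nearest coding start at 12 of 125 thresholded peaks (9.60%) against 1.81% of other peaks (odds ratio 5.76, Fisher's exact test, adjusted p = 6.85e-05 over 19 lists). Here nhr-88, nhr-19, nhr-20 and nhr-46 join the genes named in the report. These tests count peaks, and nhr-1 and nhr-14 had more than 1 each. Counted by gene, it was 10 of 208 against 0.757% of other coding genes (odds ratio 6.62, adjusted exact p = 0.00015). Location on X does not account for all of it, since autosomal peaks alone gave an odds ratio of 3.96 (6 of 88 peaks, exact p = 0.00563). The odds ratio was 5.10 against peaks matched on distance to the start (exact p = 2.69e-05) and 6.53 against peaks matched on GC (p = 3.26e-06). That SMA-9 may bind near this gene family more often than elsewhere is a hypothesis found and tested on the same data. Binding shared by many factors at these loci stays open, since no other factor was analysed here.

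The third pattern is GAGAGA, for which matches in unmasked bases alone still gave an odds ratio of 3.62 (44% against 17.8%, exact p = 5.12e-11), against masked repeats as the whole source. Summits outside the start windows gave 6.76 (59.7% against 17.97%, exact p = 1.11e-12), so position within those windows does not account for it. Strand composition stays open under the bound fixed beforehand, since 1 of the 19 other hexamers of 3 G and 3 A exceeded the 4.54 of GAGAGA, although their median was 1.24. That hexamer was AGAGAG (5.21), the same repeat read 1 base on, and without it, a choice made after the result was seen, the highest of the others was 1.93. Whether SMA-9 or another factor binds these GA tracts was not tested.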
